A study of Mus musculus with 2 samples.

How the data were processed

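H4K12la, the lactylated form of lysine 12 on histone H4, was profiled by CUT&Tag in Neuro2a cells, a mouse neuroblastoma line. CUT&Tag directs a transposase to an antibody-bound chromatin mark, so that the DNA beside the mark is cut and tagged for sequencing. One library came from cells given NaCl and 1 from cells given 25 mM lactate, each sequenced with paired reads of 150 bases per the labels' protocols. Samples were grouped by the treatment named in the labels. With 1 library per group there was no replicate error, no test between the groups was run, and every interval below covers counting error only.

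Per the submitters' processing notes, BWA, deepTools and MACS2 were used and the genome build was mm10. Tool versions, calling settings, and whether a control library or a spike-in was used are not given in the sources used here. The authors deposited 1 list of MACS2 peaks per library, called separately in each. In each list the deposited fold enrichment is the ratio of the summit pileup to the local background of that library. The deposited −log10 p and −log10 q belong to the same summit, and the deposited score is 10 times the −log10 q as a whole number. The lowest −log10 q in both lists was 1.30, which is a q threshold of 0.05. Fold, −log10 q and score are the authors' own values for each peak. They were used to describe, rank and filter peaks within a list, and fold also to recover summit pileup and relative depth and to match random gene lists. Because peaks were called within each library, the lists show where signal stood above its surroundings and carry no common scale of total H4K12la.

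Peaks on chromosomes 1 to 19, X and Y were kept. The 6 lines of the mitochondrial genome in each list were left out, and neither list repeated an interval. Read totals are not in the lists, so relative depth was worked out from the peaks. MACS2 reports a fold of (pileup + 1)/(lambda + 1) and a Poisson p of the pileup at lambda, the expected background. Solving both for each peak gave a whole-number pileup within 0.001 of the deposited −log10 p for 46591 of 46592 control peaks and all 39768 lactate peaks. The genome-wide background was 2.96 overlapping reads in the control and 3.06 in the lactate library. Local backgrounds in both libraries moved in steps of 0.02, the step that 1 read extended to 200 bp gives over a 10 kb window. With the same extension and genome size, the lactate library had 3.43% more reads after the authors' filtering than the control. The lowest summit pileup of any called peak was 11 reads in each library, so a region with no call may still hold signal below about that level, or a higher level where the local background is higher. On simulated peaks the solution returned the true pileup for 100% of 20000 peaks.

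Overlap was taken as at least 1 bp with bedtools 2.31.1. Chance overlap was measured by shifting control peaks along each chromosome 100 times. Shares have exact (Clopper-Pearson) 95% intervals and summit pileups have exact Poisson 95% intervals. Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes on the chromosomes kept. This table gives 1 start and end per gene but neither strand nor transcripts. The planned window of 1 kb on either side of the 5′ end was therefore placed at both annotated ends of each gene, and "gene end" below means either. A gene-end peak may thus lie at a promoter or at a 3′ end. Peaks that met no gene-end window were placed inside a protein-coding gene, farther than 10 kb from any annotated gene, or elsewhere. Simulated peaks placed at 200 genes were found at all 200.

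Before the data were examined, 13 gene lists, the named-gene rule and most alternatives were fixed. Each list's excess of lactate-only over control-only genes was placed among 10000 random lists of the same size, matched on the higher gene-end fold of either library in 10 bins, with genes called in neither kept apart. All 252 list entries matched a gene, 1 of them through an older symbol. The rule named the 10 genes with the highest fold called in each library alone, the 5 with the highest fold in each library among genes called in both, and every member of the POMC and energy balance lists. It also named up to 4 members of each other list called in 1 library alone, up to 2 called in both, and the 3 highest peaks far from genes in each library. Symbols beginning Gm with a number or ending in Rik were passed over in the first parts of the rule. The alternatives were stricter thresholds, lists of equal length (the highest −log10 q first), merged intervals, all contigs, other overlap criteria and other windows. Windows at every transcript start could not be made with this table. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.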

Results

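H4K12la peaks were mapped in Neuro2a cells given NaCl or 25 mM lactate, with 1 library per group, as part of a study that asks whether H4K12la regulates gene transcription. The comparison made here asks which genes and regions carry the mark in each library. The control list held 46592 peaks covering 11.7 Mb and the lactate list held 39768 peaks covering 12.3 Mb. The background recovered from the peaks put the depths within 3.43% of each other. Without replicates, each difference below is between these 2 libraries and has no replicate check.

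The libraries differed in where their peaks lay. Peaks within 1 kb of an end of a protein-coding gene numbered 7105 in the control and 10589 in the lactate library. They made up 15.2% of control peaks (95% interval 14.9% to 15.6%) and 26.6% of lactate peaks (26.2% to 27.1%), while the gene-end windows cover 2.91% of the genome. Peaks farther than 10 kb from any gene went the other way, with 14292 in the control and 5713 in the lactate library, or 30.7% (30.3% to 31.1%) against 14.4% (14.0% to 14.7%). Peaks inside genes but away from their ends were almost equal in number, 15980 against 15974. The median width was 192 bp in the control and 207 bp in the lactate library. Median fold of the gene-end peaks was 3.69 in the control and 3.57 in the lactate library. The order of the totals turned with the threshold. At a −log10 q of at least 5 the control kept 6163 peaks and the lactate library 9813.

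**Figure D1:**
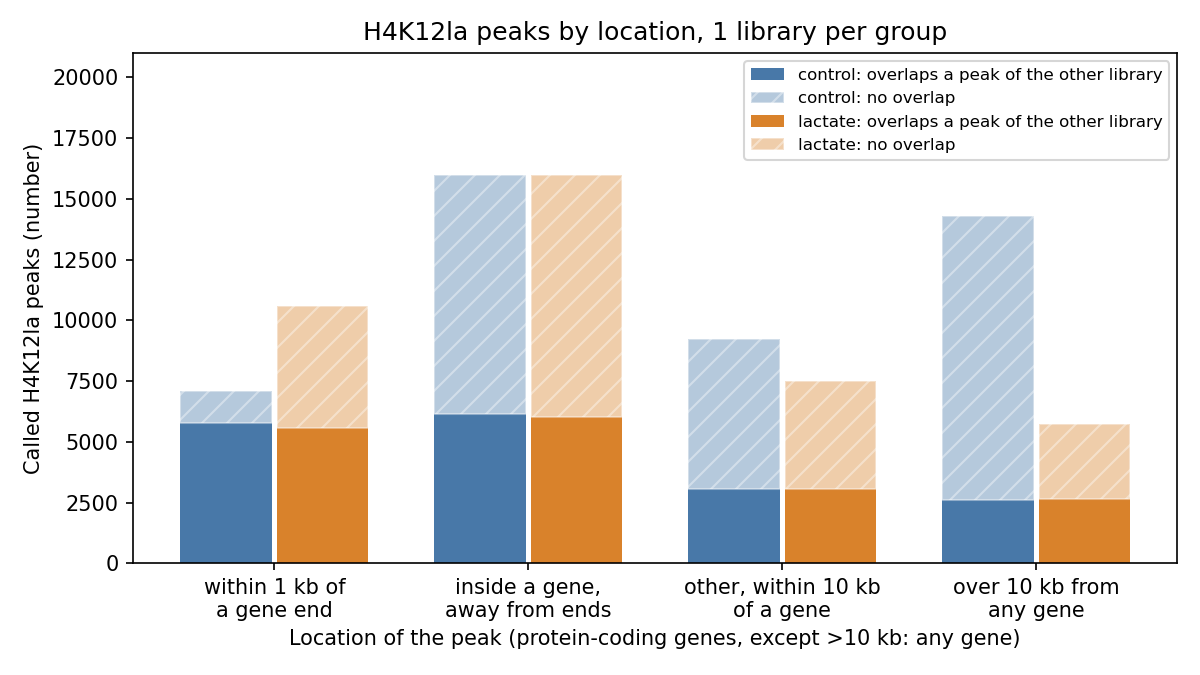
Number of called H4K12la peaks (y axis) by location (x axis) in the NaCl control and lactate libraries, 1 library each; solid bars are peaks that overlap a peak of the other library and hatched bars those that do not. The lactate library has more peaks at gene ends (10589 against 7105) and the control more peaks over 10 kb from any gene (14292 against 5713).

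Of the control peaks, 37.7% overlapped a lactate peak (37.3% to 38.1%), and of the lactate peaks 43.4% overlapped a control peak (42.9% to 43.9%). Shifted control peaks gave medians of 0.907% and 1.06%. The shifts moved peaks to any part of their chromosome. These medians therefore do not allow for a preference of both libraries for the same kinds of region, such as gene ends. The lists shared 4.66 Mb of the 19.4 Mb that either covered, a Jaccard index of 24.1%. The order of the overlap shares turned with the threshold, to 58.4% of control and 36.7% of lactate peaks at a −log10 q of at least 5. At gene ends 81.3% of control peaks had a lactate partner (80.3% to 82.2%), while 52.5% of lactate peaks had a control partner (51.5% to 53.4%). Far from genes the order was opposite, at 18.2% of control peaks (17.6% to 18.9%) and 46.1% of lactate peaks (44.8% to 47.4%). Control peaks with no lactate partner had a median summit pileup of 14 reads, and those with a partner 17 reads. In the lactate library the medians were 16 reads without a control partner and 22 with one. The highest of the far control peaks without a partner lay on chromosome 1 at 47119574 to 47120316 (mm10), with 33 summit reads (22.7 to 46.3). The next were on chromosome 8 at 60319674 to 60319930 and on chromosome 16 at 69199525 to 69200449, each with 28 reads (18.6 to 40.5). In the lactate library the highest without a control partner were on chromosome 9 at 90863113 to 90863527 with 28 reads (18.6 to 40.5), chromosome 12 at 31580891 to 31581408 with 25 reads (16.2 to 36.9) and chromosome 1 at 22002335 to 22002646 with 23 reads (14.6 to 34.5).

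Per gene, a gene-end peak was called for 6996 of 21887 protein-coding genes in the control and 9802 in the lactate library. Both libraries called 6266 genes, the lactate library alone 3536 and the control alone 730. The lactate library thus held 82.9% of the 4266 genes called in 1 library (81.7% to 84.0%). Median summit pileups were 19 reads at the lactate-only genes and 14 reads at the control-only genes, against a lowest callable pileup of 11 reads. At a −log10 q of at least 10 in both lists, 975 genes were called in the lactate library alone and 62 in the control alone. Cutting both lists can turn a gene with a weaker peak in the other library into a one-library gene. With a −log10 q of 5 in the gene's own library and no other-library peak, 930 genes were lactate-only and 29 control-only. A best peak shared with another gene was found for 2440 genes in the lactate library and 1766 in the control, since windows of neighbouring genes overlap.

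**Figure D2:**
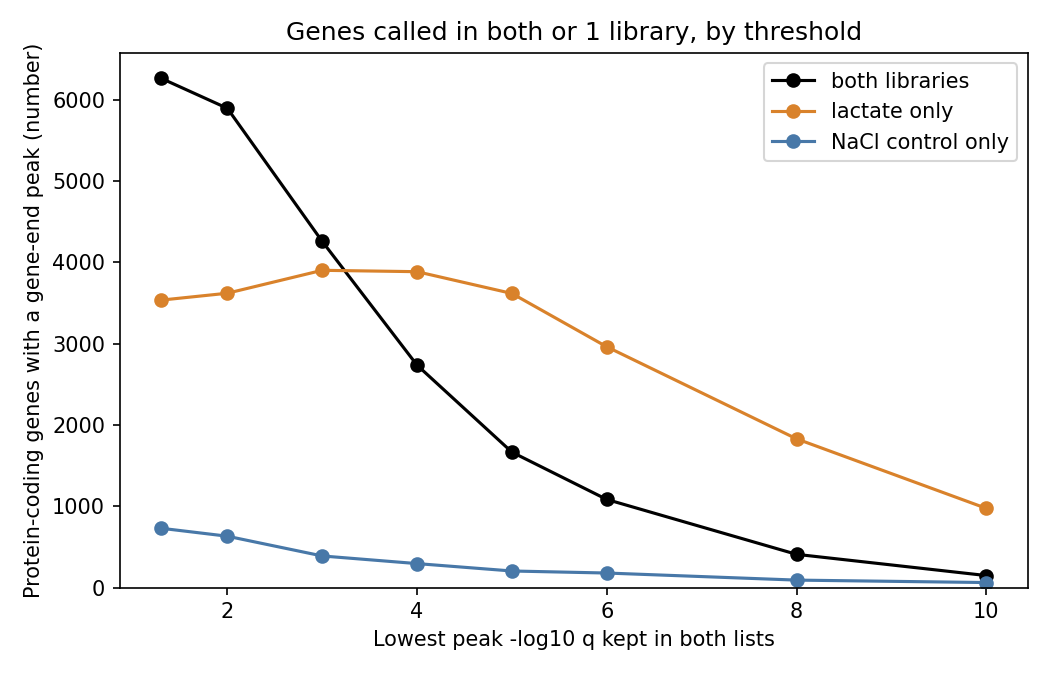
Number of protein-coding genes with a gene-end H4K12la peak (y axis) against the lowest −log10 q kept in both lists (x axis), for genes called in both libraries, the lactate library alone or the NaCl control alone (1 library per group). Lactate-only genes outnumber control-only genes at every threshold drawn, from 3536 against 730 with all peaks to 975 against 62 at a −log10 q of 10. Where the lists are cut, the one-library counts can include genes with a weaker peak in the other library.

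The 10 highest-fold genes called in the lactate library alone were Sfr1, Ccdc82, Zfp809, Trim24, Rcn2, Spata7, Fbxo47, Pin4, Mtmr6 and Lman1. Their fold enrichments ran from 7.39 at Sfr1 to 6.20 at Lman1. Sfr1, which encodes a recombination repair factor, had its peak on chromosome 19 at 47731110 to 47731977, across the lower-coordinate end of the gene (47731714 to 47735588), with 29 summit reads (19.4 to 41.6). Trim24, which encodes a bromodomain chromatin reader, had 27 summit reads at chromosome 6, 37870494 to 37870854. Zfp809, a KRAB zinc finger repressor of retroviral sequences, also had 27 reads. Lman1, a cargo receptor between endoplasmic reticulum and Golgi, had 29 reads, and Mtmr6, a phosphoinositide phosphatase, had 32 reads (21.9 to 45.2). All 10 of these peaks touched the annotated gene, and none lay within 1 kb of the end of another protein-coding gene. Sfr1 and Ccdc82 nonetheless have an end window that overlaps that of another gene. The control had peaks elsewhere in Trim24, Mtmr6 and Lman1, that of Mtmr6 within 3 kb of a gene end.

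The 10 highest-fold genes called in the control alone were Defa35, Crisp4, Defa3, Olfr824, Mup17, Naaladl1, Galnt5, Ptgs2, Dgkb and Sntn. They include Paneth cell defensins (Defa35 and Defa3), an odorant receptor (Olfr824), a major urinary protein (Mup17) and a gene of the epididymis (Crisp4). Fold ran from 6.82 at Defa35, with 26 summit reads (17.0 to 38.1), to 4.98 at Dgkb and Sntn, with 20 reads each. Ptgs2, which encodes the inducible cyclooxygenase, had 19 reads (11.4 to 29.7) at chromosome 1, 150100159 to 150100363. Of these genes, Defa35, Crisp4 and Defa3 alone reached a −log10 q of 10, which all 10 of the lactate-only genes above reached. The peaks credited to Crisp4, Olfr824, Naaladl1 and Sntn did not touch the gene itself. Naaladl1 had a lactate peak within 3 kb and has an end window that overlaps that of another gene. Defensin, odorant receptor and urinary protein genes have near-identical copies, so reads there may be split or shared between copies.

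Among genes called in both libraries, the same 5 had the highest fold in each list: Wls, Oasl1, Arhgap25, Adgrf2 and Lars2. The Wls peak, on chromosome 3 beyond the higher-coordinate end of the gene, had a fold of 24.9 and 146 summit reads in the control (123 to 172), and a fold of 25.3 and 150 reads in the lactate library (127 to 176). It lay outside the window when that was 500 bp. The peaks at Oasl1 and Arhgap25 also lay outside the gene, while those at Adgrf2 and Lars2 touched it. No filter for repeated sequence was applied here, and whether the peaks at these 5 genes reflect the mark or read mapping was not tested. Lars2, the mitochondrial leucyl-tRNA synthetase, had 66 reads in the control (51.0 to 84.0) and 94 in the lactate library (76.0 to 115). These intervals overlapped, which does not show that the counts are equal.

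In the list of POMC processing and secretory granule genes, 9 of 12 members were called in the lactate library and 4 in the control. Pomc itself, the precursor of alpha-MSH, was called in the lactate library alone, with a fold of 5.40 and 26 summit reads (17.0 to 38.1). This peak covered 617 bp at chromosome 12, 3959794 to 3960410, inside the gene at its higher-coordinate end (gene 3954945 to 3960643), where the window overlaps that of a neighbouring gene. Also lactate-only were the prohormone convertases Pcsk1, with 18 reads (10.7 to 28.4), and Pcsk2, with 13 reads, the convertase inhibitor precursor Pcsk1n, with 17 reads (9.90 to 27.2), and the granin Scg2, with 12 reads. Of these 5, Pomc and Pcsk1n reached a −log10 q of 5, at 9.46 and 5.03, and neither reached 10. Both have an end window that overlaps that of another gene. Pcsk2 and Scg2 had no call when the lists were cut to equal length. Pcsk1 had a control peak within 3 kb, and Pcsk1 and Pcsk2 had control peaks elsewhere in the gene. Carboxypeptidase E (Cpe), the amidating enzyme Pam, the alpha-MSH-degrading Prcp and the Pcsk2 chaperone Scg5 were called in both. Pam had 17 summit reads in the control (9.90 to 27.2) and 21 in the lactate library (13 to 32.1), at its higher-coordinate end on chromosome 1. Cpe had 17 reads in the control (9.90 to 27.2) and 36 in the lactate library (25.2 to 49.8). For both Pam and Cpe the intervals overlapped, which does not show that the counts are equal. The Prcp peak also lay at an end of the neighbouring gene Ddias. Cartpt, Furin and Chga had no gene-end peak in either library, and Furin had a lactate peak elsewhere in the gene. The excess of 5 lactate-only genes stood at percentile 97.3 of the matched random lists, whose median excess was 2, as a description of these libraries and the highest of the 13 lists.

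In the appetite and energy balance list, 4 of 22 genes were called in both libraries, 3 in the lactate library alone and 1 in the control alone, and the list stood at percentile 43.5. The 4 were the insulin receptor Insr, the leptin signal transducer Stat3, Fto and Agrp. Stat3 had 15 summit reads in the control (8.40 to 24.7) and 36 in the lactate library (25.2 to 49.8), and Insr had 26 reads (17.0 to 38.1) and 40 reads (28.6 to 54.5). On counting error alone, the intervals did not overlap for Stat3 and overlapped for Insr. Over all genes called in both, median summits were 17 reads in the control and 26 in the lactate library, so higher lactate counts were not particular to Stat3. Stat3 also has an end window that overlaps that of another gene. The Agrp peak did not touch that gene and lay at an end of Atp6v0d1, and the Fto peak also lay at an end of Rpgrip1l. Fam172a, named in the study's title, was called in the lactate library alone with 16 reads (9.15 to 26.0) at chromosome 13, 77708670 to 77708869. Its −log10 q of 4.38 did not reach 5, and the control had a peak elsewhere in the gene. Igf1r and Sim1 were lactate-only with 11 and 12 reads, and the leptin feedback inhibitor Socs3 was control-only with 11 reads (5.49 to 19.7), all close to the lowest callable pileup, and Igf1r had a control peak elsewhere in the gene. The remaining 14 had no gene-end call: Lepr, Mc3r, Mc4r, Npy, Ghsr, Glp1r, Htr2c, Ptpn1, Foxo1, Nhlh2, Bdnf, Ntrk2, Adcyap1 and Nr3c1. Away from the gene ends, Lepr, Ptpn1, Bdnf, Ntrk2 and Nr3c1 had peaks in both libraries, Glp1r in the lactate library and Htr2c in the control.

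Energy metabolism genes were called often in both libraries. Of 27 glycolysis and lactate genes, 14 were called in both, 7 in the lactate library alone, none in the control alone and 6 in neither. The lactate-only members with the highest fold were Pdk1, a kinase that inhibits pyruvate dehydrogenase, with 20 summit reads, the glucose transporter Slc2a1 with 19, pyruvate kinase Pkm with 20 and the mitochondrial pyruvate carrier subunit Mpc1 with 23. Of all 7, Pdk1, Slc2a1 and Mpc1 reached a −log10 q of 5. Pdha1 and Pfkp were called in both. Of 20 TCA cycle and oxidative phosphorylation genes, 14 were called in both and 4 in the lactate library alone, which were Uqcrfs1, Ndufv1, Sdhb and Ndufs1. Sdhb, a succinate dehydrogenase subunit, had 44 lactate reads (32.0 to 59.1). Its partner Sdha was called in both, with 32 reads in the control and 43 in the lactate library. Fold at Sdha ran the other way, at 5.39 in the control and 4.21 in the lactate library. Sdhb and Uqcrfs1 reached a −log10 q of 5, and the control had a peak elsewhere in Sdhb. The percentiles were 72.3 for glycolysis and 41.2 for the TCA cycle list.

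Among 19 histone acyltransferase and deacylase genes, 9 were called in both libraries and 5 in the lactate library alone. The lactate-only genes named by the rule were the deacetylases Sirt3, with 27 summit reads, and Hdac3, with 18, and the acetyltransferases Crebbp, with 24, and Hat1, with 19. Of all 5, Sirt3 and Crebbp reached a −log10 q of 5, and the control had peaks elsewhere in Sirt3, Crebbp and Hat1 and within 3 kb of an end of Hdac3. Hdac2 and Acss2 were called in both. The hypoxia list had 4 of 13 genes in both and 4 in the lactate library alone, Bnip3, Ddit4, Adm and Egln1. Among those called in both, Ankrd37 and P4ha1 came first by the higher fold of either library. Bnip3 and Ddit4 reached a −log10 q of 5, and the control had a peak within 3 kb of an end of Ddit4 and one inside Egln1. Immediate early genes had 2 of 13 in both, Jun and Arc, and 6 in the lactate library alone. Among these 6, Egr1 had 18 reads, Dusp1 20, Atf3 14 and Fos 14. None of the 6 reached a −log10 q of 5. Of Egr1, Dusp1, Atf3 and Fos, Dusp1 alone kept its call when the lists were cut to equal length. These lists had no control-only gene and stood at percentiles 74.3, 85.9 and 84.6.

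Of 20 cell cycle genes, 11 were called in both libraries, Mcm3 and Mcm4 among them, and 7 in the lactate library alone. Of those 7, Mcm5, of the replicative helicase, had 30 summit reads, cyclin E1 (Ccne1) 21, Cdk2 19 and Top2a 17. Mcm5 alone of the 7 reached a −log10 q of 5, and the control had a peak elsewhere in Mcm5 and within 3 kb of an end of Cdk2. The ribosome and housekeeping list had 7 of 18 genes in both, including Rpl5 and Eef1a1, and 7 in the lactate library alone, including Rps6, B2m, Rplp0 and Rps3. Of those 7, Rps6 reached a −log10 q of 5, and Rplp0 had a control peak within 3 kb. Neither list had a control-only gene, and their percentiles were 76.6 and 75.7. The lactate-only share was thus 7 of 18 for housekeeping genes, beside 7 of 27 for glycolysis and 4 of 20 for the TCA cycle list.

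Of 23 neuronal and neuroblastoma identity genes, 5 were called in both libraries, 5 in the lactate library alone, 1 in the control alone and 12 in neither. The lactate-only genes included Elavl4, a neuronal RNA-binding protein, with 22 summit reads, and the noradrenergic regulator Phox2a, with 25, besides Rbfox3 and Gap43 with 16 and 14. Elavl4 alone of the 5 reached a −log10 q of 5, and the control had peaks elsewhere in Elavl4, Rbfox3 and Gap43. Syt1 and Map2 were called in both. Of 16 neurotransmitter receptor and channel genes, Grin1 was the single lactate-only gene, and 4 were called in both, including Cacna1b. The percentiles were 68.8 and 36.6. Developmental transcription factors were mostly without a call, 21 of 24, with Hoxc9 and Lhx2 lactate-only and Pax6 control-only (percentile 34.9). Markers of other cell types, listed as genes foreign to this line, had no call at 24 of 25 genes. The exception was the myelin gene Mbp in the lactate library, with 15 reads (8.40 to 24.7), and that list stood at percentile 64.5. These 25 genes are too few to measure how often stray calls occur. In a larger family examined later, 72 of 1110 olfactory receptor genes were called in the control alone. The calls at Grin1, Hoxc9, Lhx2, Pax6 and Mbp did not reach a −log10 q of 5, and the lactate library had a peak elsewhere in Pax6.

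**Figure D3:**
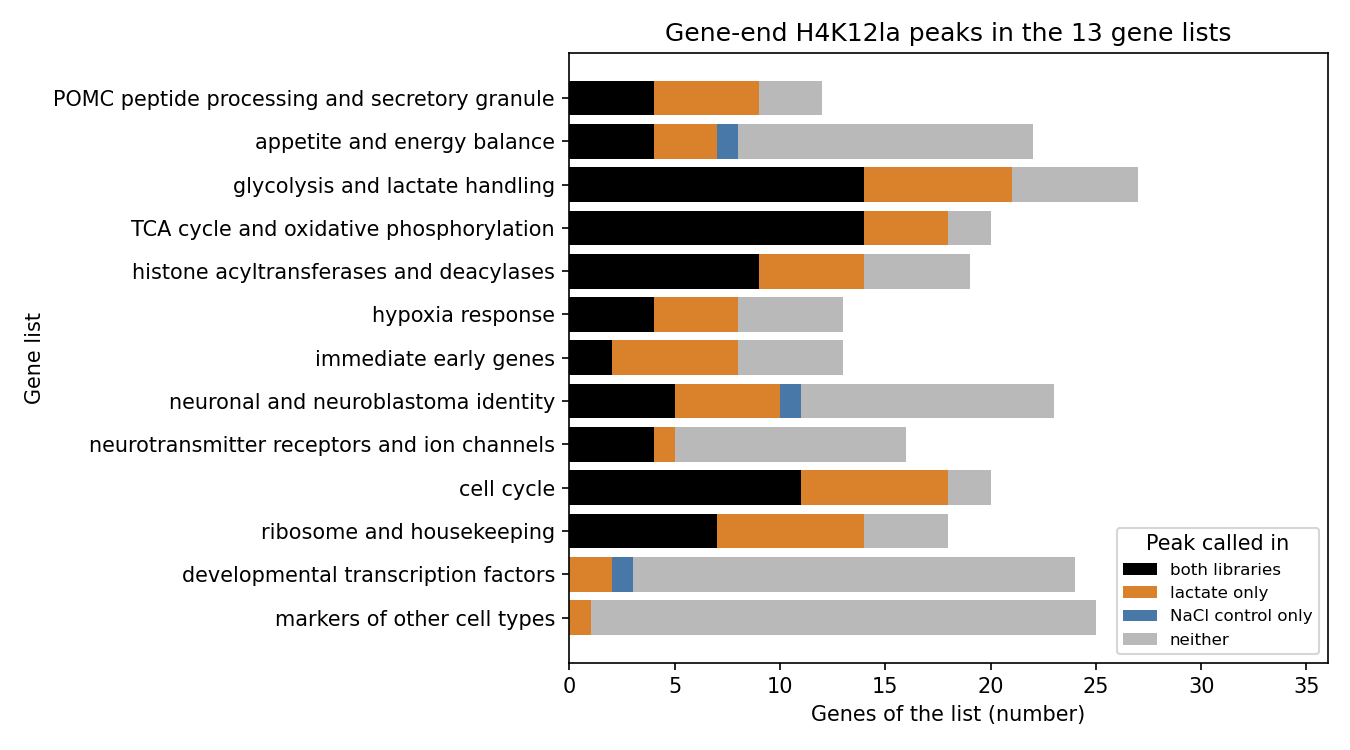
Number of genes (x axis) in each of the 13 gene lists (y axis) whose gene end had an H4K12la peak in both libraries, the lactate library alone, the NaCl control alone or neither (1 library per group). In total 78 listed genes were called in both libraries, 57 in the lactate library alone, 3 in the control alone and 114 in neither.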

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

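The excess of lactate-only over control-only genes kept its direction under the alternatives run for it. These were both thresholds, equal lists, both other windows, the threshold in the gene's own library and the 3 added after seeing the data. Each of them only removes calls or only widens the windows. No named gene called in 1 library could therefore become a call of the other library alone. Where a value below moved, the cause was not tested beyond what the setting itself removes or adds. At a −log10 q of at least 5, the control and lactate lists held 6163 and 9813 peaks, 58.4% and 36.7% of them overlapped the other list, 26.3% and 47.5% lay at gene ends, and the Jaccard index was 25.6%. Genes in both then numbered 1666 and control-only genes 204, and the gene lists held 25 genes in both and 1 control-only. At a −log10 q of at least 10 the values were 1201 and 1947 peaks, 63.1% and 38.9% overlapping, 48.9% of lactate peaks at gene ends, and a Jaccard index of 26.4%. Genes numbered 148 in both, 62 control-only and 975 lactate-only, and the lists held 1, 0 and 17. With both lists cut to their 19884 best peaks, 45.7% and 45.3% overlapped, 20.3% and 37.3% lay at gene ends, the Jaccard index was 26.9%, and genes in both and control-only were 4018 and 402. A fold of at least 5 left 2496 control and 2231 lactate peaks. The overlap shares were 21.2% and 24.9% when 50% of both peaks had to overlap, 30.6% and 29.6% for 50% of the peak itself, 31.9% and 37.4% for summits within 200 bp, and 44.1% and 53.5% with the other list extended by 1 kb. Windows of 500 bp put 12.8% and 22.3% of peaks at gene ends. Windows of 3 kb put 20.3% and 33.5% there, with 1105 control-only genes and 5 control-only list genes. Requiring a −log10 q of 5 in the gene's own library left 29 control-only and 930 lactate-only genes. Of the alternatives added after seeing the data, a summit pileup of at least 22 reads left 23 and 1224, and leaving out genes that share an end window gave 3442 in both and 1919 lactate-only. This left out 15 of the 54 named lactate-only genes. They were Pomc, Pcsk1n, Sfr1, Ccdc82, Igf1r, Pkm, Ndufv1, Ndufs1, Sirt3, Hdac3, Rbfox3, Phox2a, Grin1, Cdk2 and Rplp0. With whole gene bodies, 9327 genes were called in both, 1054 in the control alone and 3279 in the lactate library alone, and 16 of the 54 were called in both, namely Fam172a, Pcsk1, Pcsk2, Igf1r, Trim24, Mtmr6, Lman1, Sdhb, Sirt3, Crebbp, Hat1, Egln1, Elavl4, Rbfox3, Gap43 and Mcm5. Of the same 54 genes, 24 remained lactate-only at a −log10 q of 5, 36 with equal lists and 46 with the 3 kb window. Of the 31 named genes called in both, 11 became lactate-only at a −log10 q of 5 and 1, Jun, became control-only with equal lists. Windows at every transcript start were not run, since transcript starts were not used here. No paired analysis was possible because each group has 1 library. Depth limits the calls to summits of at least 11 reads, so a missing call is no evidence of absent signal.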

Other observations

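All families and tests in this part were chosen after their results were seen, except the test of chromosome copy number. Of 12 gene families examined, some had more control-only and others more lactate-only genes. Over all protein-coding genes, 28.6% were called in both, 16.2% in the lactate library alone and 3.34% in the control alone. As 82.9% of all one-library genes were lactate-only, a lactate-only majority within a family was the general pattern. Of 1110 olfactory receptor genes, 72 had a gene-end peak in the control alone, 10 in the lactate library alone and 7 in both. Of 355 vomeronasal receptor genes, 18 were control-only, 2 lactate-only and 7 in both, and of 70 defensin genes 7 were control-only, 0 lactate-only and 8 in both. These families belong to sensory neurons and epithelia, and many members have near-identical copies. Among 397 Zfp zinc finger genes, 214 were called in both, 74 in the lactate library alone and 12 in the control alone. Mitochondrial ribosomal protein genes were called in both for 50 of 78, in the lactate library alone for 19 and in the control alone for 1. Cytosolic ribosomal protein genes had 43 of 98 in both, 34 lactate-only and 3 control-only, and translation initiation factor genes 35 of 56, 13 and 1. Mediator subunit genes had 13 of 30 in both, 12 lactate-only and 1 control-only, centrosomal protein genes 23 of 38, 10 and 0, and vacuolar sorting genes 22 of 35, 7 and 1. Interleukin and keratin genes showed no clear split, with 11 of 83 in both, 4 lactate-only and 6 control-only, and 2 of 53 in both, 0 lactate-only and 1 control-only. No test separates these families, since each group has 1 library.

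Greater depth of the lactate library does not account for the excess of genes called in it alone, 3536 against 730, since depths differed by 3.43% and peaks far from genes were 0.400 times as many as in the control. Calls near the detection limit stay open. Summit pileups of at least 22 reads were found at 1224 lactate-only and 23 control-only genes, which decides nothing, as median summits at genes called in both were already 26 reads in the lactate library and 17 in the control. A lower signal over background in the control library also stays open. It predicts control-only calls at genes silent in these cells, and 90 olfactory and vomeronasal receptor genes were control-only against 12 lactate-only. Few of these receptor genes had a lactate call, so a control call there was mostly control-only. Among genes without a lactate call, 72 olfactory receptor genes were control-only beside 1021 in neither, and 18 vomeronasal beside 328. Over all protein-coding genes the counts were 730 beside 11355, a similar proportion, so control-only calls did not favour these receptors. A rise of the mark at genes under lactate was not tested, since the 82.9% of one-library genes in the lactate library is the pattern itself, and with 1 library per group and no known spike-in these explanations cannot be told apart.

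Control peaks farther than 10 kb from genes were unevenly spread, from 1.61 per Mb on chromosome 19 to 11.6 per Mb on chromosome 15, with Y left out at 0.209 per Mb. Density was taken over the whole chromosome length, not over the sequence farther than 10 kb from genes. A chromosome rich in genes can therefore score lower in both libraries for that reason alone. The lactate library ranked the 20 chromosomes alike (Pearson r = 0.93, Spearman rho = 0.95, each permutation p = 2e-05, the smallest these permutations can give, adjusted 4e-05, and r = 0.91 without the 2 chromosomes farthest from the median). A candidate explanation is the copy number of the chromosomes in this aneuploid line, which would also raise the share of genes called. Control far-peak density did go with the share of genes called in the lactate library over 20 chromosomes (rho = 0.69, permutation p = 0.00112, adjusted 0.00112, and r = 0.56, p = 0.0048, adjusted 0.0048, r = 0.56 without the 2 farthest). Both relations were 2-sided and are the 2 computed, and chromosomes are not replicates, so other properties of whole chromosomes, gene density among them, may act in the same way.

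All 100 highest-fold control peaks, with folds of at least 11.4, overlapped a lactate peak, and all 100 highest-fold lactate peaks overlapped a control peak. These peaks were picked by rank, so the counts describe these lists and no interval is given. In each library 3 of these 100 lay at a gene end, and 32 in the control and 36 in the lactate library lay farther than 10 kb from any gene. No filter for repeated sequence was applied here, so this overlap may reflect read mapping as well as the mark, which was not tested.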
